A study of Mus musculus with 8 samples.

How the data were processed

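RNA-seq libraries of polyadenylated RNA from mouse inguinal white adipose tissue were compared between 4 wild-type and 4 Fabp4-Ebf2 samples, prepared with TRIzol and TruSeq kits from animals about 6 weeks old, per the labels. The labels do not state that each library came from a separate animal, so p-values measure the spread between these samples. The deposited table held read counts for 28644 RefSeq transcripts, made by the authors against the mm9 genome per the submitters' processing notes. The aligner, the counting program and the use of strand are not given in the sources used here, so reads shared between overlapping or near-identical genes may be split or counted for each. The table also held, per the file headers, the authors' edgeR log2 fold change for each transcript. The authors' FDR, an adjusted p-value from edgeR per the file headers, was given for the same transcripts. A further 8 per-sample columns of log2 values deposited under the same column names as the counts were not used, since their processing is not stated.

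A gene was represented by the transcript that the authors marked as best (21967 genes) or, where none was marked (902 genes), by the transcript with most reads, since transcripts of 1 gene share reads. This gave 22869 genes, of which 3705 had more than 1 transcript. Library totals over these genes ran from 16.9 to 24.7 M reads. A count of 3 reads corresponded to 0.116 to 0.178 CPM. The biological coefficient of variation was 18.7%, well above counting error for genes of moderate level, so the spread between samples rather than depth limited most genes.

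Genes were tested in edgeR 4.0.16 (R 4.3.3) with TMM factors (0.941 to 1.07), the filterByExpr filter (15002 genes kept), glmQLFit and glmQLFTest with genotype as the only term, and Benjamini-Hochberg adjustment at 0.05. Standard errors of log2 fold changes were the absolute log2 fold change divided by the square root of the F statistic. Of the tested genes 2625 had an unadjusted p under 0.05. The 22 gene lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the lists. The genotype comparison, its test, the gene lists and the alternatives not marked as added were fixed before the data were examined. Named genes were Ebf2, 12 adipocyte genes given whatever their result, the 8 highest and 8 lowest log2 fold changes among genes past the threshold with non-overlapping groups and a mean of at least 1 CPM in 1 group, and the members with the smallest p of each list. Up to 4 members were named for lists with at least 3 members past the threshold or past camera, and up to 2 for the others. Genes named beyond that rule were chosen after their values were seen, and some results for single genes are not reported here.

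RefSeq genes of GRCm38, which is not the build the authors used, served only for gene names, neighbours and chromosomes, and placed 14895 tested genes (99.3%). Positions in that build served only to order genes along chromosomes. Simulated counts with 200 changed genes were used to test the procedure. It recovered 27 of 67 genes changed 1.5-fold, 46 of 67 changed 2-fold and 62 of 66 changed 4-fold, with 9 unchanged genes called. With none changed, 0 genes and 0 lists were called by edgeR and camera. Genes were simulated independently of each other, so the simulation cannot show how camera behaves for lists whose members vary together. In the real data the estimated correlation was 0.81 for the tricarboxylic acid cycle list, against the preset 0.01.

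Alternatives were DESeq2 1.42.0, limma-voom, other normalisation factors and filters, a block on replicate number, 3 marker lists as covariates, a 1.5-fold threshold, each library left out in turn, and camera with an estimated correlation or fry for the lists. Other transcript choices, edgeR's exact test, robust dispersion, leaving out both doubted libraries, and an exact permutation test of list means were added after the data were seen. Figures were drawn with matplotlib 3.10.9. In the authors' deposited table, 682 of the transcripts kept here were higher and 277 lower at FDR under 0.05, and 472 of the 513 genes called here were among them in the same direction.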

Results

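Gene expression was measured by RNA-seq of polyadenylated RNA from inguinal white adipose tissue, the subcutaneous fat depot of the mouse groin. Mice carrying a Fabp4-Ebf2 transgene were compared with wild-type mice. EBF2 is a transcription factor enriched in brown and beige fat cells, and Fabp4 regulatory sequence is active in adipocytes. There were 4 libraries per genotype, all from animals of mixed background aged about 6 weeks. The wild-type libraries held 19.3, 24.1, 22.1 and 16.9 M reads over 22869 genes, and the Fabp4-Ebf2 libraries held 21.7, 23.2, 18.4 and 24.7 M. The most abundant gene of a library, Scd1 in 6 libraries, took 1.44 to 3.55% of its reads. Levels are given as CPM, the reads of a gene scaled to a common library total after TMM normalisation, as mean ± SD with n = 4 per genotype. The comparison asked how raised Ebf2 in fat changed the transcripts of this depot, in particular those of thermogenic adipocytes.

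Ebf2 itself was 15.7-fold higher in Fabp4-Ebf2 fat. Its level was 438 ± 148 CPM (n = 4) against 27.9 ± 9.30 CPM in wild type (n = 4), a log2 fold change of 3.98 with a standard error (SE) of 0.35 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.00177). The Fabp4-Ebf2 libraries lay between 231 and 575 CPM and the wild-type libraries between 14.9 and 37.0 CPM. A two-sided exact permutation test on the log2 levels gave p = 0.0286, the smallest that the 70 arrangements of 8 libraries allow. Reads from the transgene and from the endogenous gene are not separated in these counts. The paralogs Ebf1, Ebf3 and Ebf4 had log2 fold changes of 0.16, -0.15 and 0.04 and did not pass the test. The Y-linked genes Uty, Kdm5d, Ddx3y and Eif2s3y were expressed in all 8 libraries with log2 fold changes of 0.01 to 0.35, none past the test, and Xist had 2 to 7 reads per library. Replicate 2 had the least Ebf2 of the Fabp4-Ebf2 libraries. With the skeletal muscle markers described further on as a covariate, the log2 fold change of Ebf2 was 3.78 (SE 0.60) and no longer passed (edgeR adjusted p = 0.134). The list mean of those markers did not overlap between the genotypes, so this covariate cannot be cleanly separated from genotype.

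Thermogenic genes formed the group with the largest rises. Of 35 tested members of a fixed list of brown and beige adipocyte genes, 24 rose, 0 fell and 11 did not pass. Adjusted over the list alone, 28 rose and 2 fell, the latter being Lhx8 and Cyp2b10. Ucp1, the uncoupling protein through which brown and beige fat makes heat, went from 35.1 ± 42.6 to 1146 ± 729 CPM, a log2 fold change of 5.03 (SE 0.91, edgeR adjusted p = 0.0213). Cidea, a lipid droplet protein abundant in brown fat, rose 6.32-fold from 76.0 ± 29.7 to 480 ± 194 CPM (edgeR adjusted p = 0.00688). The respiratory chain subunits Cox7a1 and Cox8b, abundant in brown fat and muscle, rose with log2 fold changes of 3.58 (SE 0.43) and 1.77 (SE 0.33). Cpt1b, the muscle and brown fat enzyme that commits fatty acids to mitochondrial import, rose 17.5-fold, to 403 ± 159 CPM from 23.1 ± 13.4 CPM. It overlaps BC090627, a transcript reading through from Chkb into Cpt1b, so that reads may be shared between the pair. The nuclear receptor gene Esrrg rose by 3.14 on the log2 scale (SE 0.29), and Slc27a2, a fatty acid transporter and acyl-CoA synthetase, by 4.54 (SE 0.35). Prdm16, a coregulator of brown fat identity, had 19.3 ± 4.50 CPM in Fabp4-Ebf2 against 20.8 ± 6.91 CPM in wild type (log2 fold change -0.11, SE 0.27, edgeR adjusted p = 0.862). Ppargc1a (log2 fold change 1.16, SE 0.38), Dio2 (2.06, SE 0.81) and Elovl3 (1.12, SE 0.95) had higher means that did not pass, at edgeR adjusted p = 0.142, 0.225 and 0.563. In the authors' edgeR comparison their FDR was 0.00113, 0.00372 and 0.618, so the calls of Ppargc1a and Dio2 depended on the test. Dio2 was at 48.6 CPM in Fabp4-Ebf2 replicate 1 against 6.71 to 12.3 CPM in the other Fabp4-Ebf2 libraries. Elovl3 was at 7.51 CPM in wild type replicate 1 against 0.179 to 0.951 CPM in the other wild-type libraries.

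The list as a whole was shifted upward against all other genes by camera, a competitive gene set test (adjusted p = 2.43e-23 over 22 lists), with adjusted p = 0.239 with an estimated correlation. Its mean was 5.78 ± 0.46 log2 CPM in Fabp4-Ebf2 and 3.79 ± 0.44 log2 CPM in wild type, without overlap between the libraries (two-sided exact permutation p = 0.0286, the smallest possible, and 0.0786 after adjustment over the lists). The skeletal muscle list moved the other way in the same libraries, by a median log2 fold change of -1.99. Without wild type replicate 3 or 4, 13 and 14 members rose instead of 24. The log2 fold change of Ucp1 was 6.37 without wild type replicate 1, which had the most Ucp1 of its group. Ucp1 did not pass without wild type replicate 3 or 4 or Fabp4-Ebf2 replicate 1 (edgeR adjusted p = 0.0648, 0.0779 and 0.0545), and Cox8b without any of these or wild type replicate 2 (0.0555 to 0.0693).

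**Figure D1:**
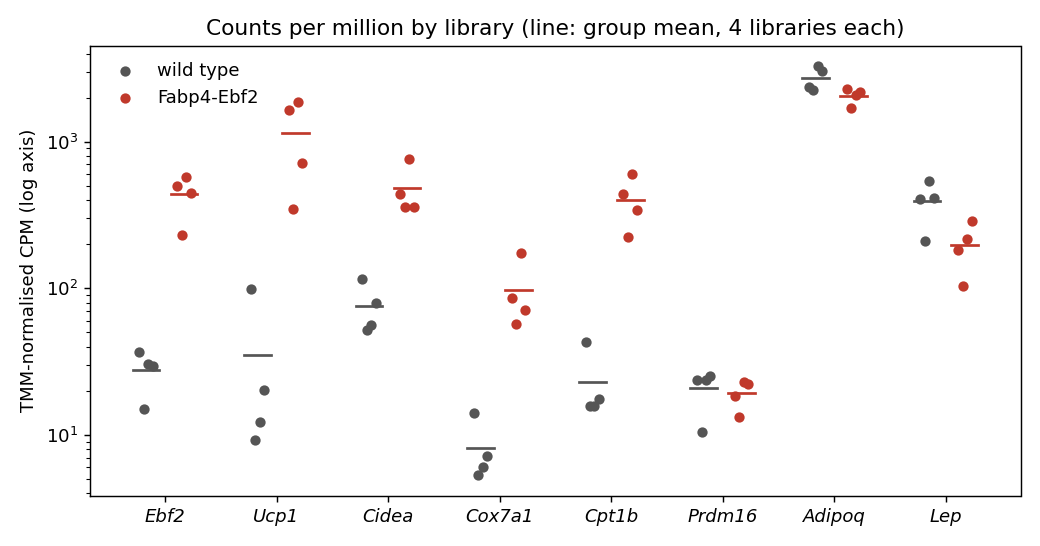
TMM-normalised CPM, on a log axis, of 8 genes in each of the 4 wild-type (grey) and 4 Fabp4-Ebf2 (red) libraries, with lines at the group means. Ebf2 lay between 231 and 575 CPM in Fabp4-Ebf2 and between 14.9 and 37.0 CPM in wild type, whereas the libraries of both groups overlapped for Prdm16, Adipoq and Lep.

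Genes of mitochondrial fuel oxidation rose together, by smaller factors. For fatty acid oxidation, 19 of 28 tested genes rose and 0 fell, with a median log2 fold change of 1.06. For the tricarboxylic acid cycle and pyruvate dehydrogenase, 20 of 25 rose and 0 fell, with a median of 1.00. For the nuclear-encoded subunits of oxidative phosphorylation, 56 of 76 rose and 0 fell, with a median of 0.71. Adjusted over the list alone, 24, 23 and 70 members rose, and 2 of the last list fell, the ATP synthase c-subunit genes Atp5g1 and Atp5g3. Acaa2, the last enzyme of the mitochondrial β-oxidation spiral, rose 5.61-fold from 157 ± 23.9 to 882 ± 344 CPM (edgeR adjusted p = 0.00282). The very-long-chain acyl-CoA dehydrogenase Acadvl rose 3.24-fold and the carnitine-acylcarnitine carrier Slc25a20 rose 2.77-fold. The succinyl-CoA ligase subunit Sucla2 rose 3.72-fold, and isocitrate dehydrogenase Idh2 rose 2.31-fold from 129 ± 8.45 to 299 ± 73.6 CPM (edgeR adjusted p = 0.00805). Among respiratory chain subunits, Ndufb8 of complex I rose 2.25-fold from 139 ± 8.19 to 312 ± 50.4 CPM (edgeR adjusted p = 0.00282), Cyc1 of complex III rose 2.22-fold and Cox5a of complex IV rose 2.06-fold.

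All 3 lists passed camera, at adjusted p = 1.66e-22 for fatty acid oxidation, 2.43e-23 for the tricarboxylic acid cycle and 1.17e-43 for oxidative phosphorylation, each with adjusted p = 0.239 with an estimated correlation. The oxidative phosphorylation mean was 7.13 ± 0.24 log2 CPM in Fabp4-Ebf2 and 6.48 ± 0.04 log2 CPM in wild type, and no Fabp4-Ebf2 library overlapped with wild type in any of these lists (exact permutation p = 0.0286 each). Skeletal muscle markers were lower in these Fabp4-Ebf2 libraries by a median log2 fold change of -1.99. The members shared with another list were Cpt1b and Acot2 (thermogenic and fatty acid oxidation) and Sdha, Sdhb, Sdhc and Sdhd (cycle and respiratory chain). Fewer members passed without wild type replicate 3, wild type replicate 4 or Fabp4-Ebf2 replicate 1, at 9, 10 and 11 for fatty acid oxidation, 6, 6 and 8 for the cycle, and 9, 11 and 20 for oxidative phosphorylation. Oxidative phosphorylation also had 30 without wild type replicate 1.

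**Figure D2:**
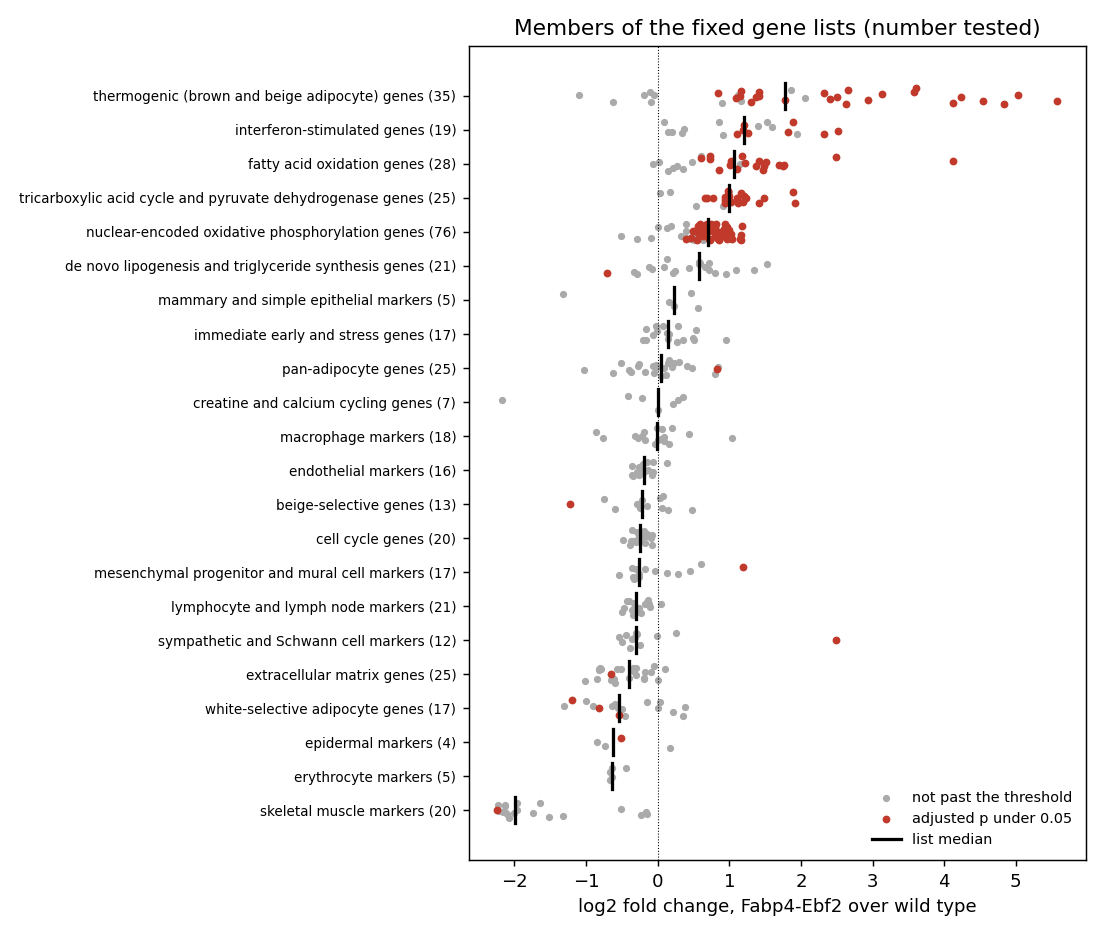
Log2 fold changes, Fabp4-Ebf2 over wild type, of the tested members of the 22 gene lists, with the number tested in brackets. Red points passed the threshold, grey points did not, and the black line is the list median, which ran from 1.77 for thermogenic genes to -1.99 for skeletal muscle markers.

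A minority of the genes that mark white rather than thermogenic adipocytes fell, and most general adipocyte genes did not pass the test. Of 17 tested white-selective genes, 3 fell, 0 rose and 14 did not pass, and 7 fell when adjusted over the list alone. The amino acid transporter Slc7a10 fell (edgeR adjusted p = 0.00805), from 284 ± 51.0 to 124 ± 18.9 CPM. The adipokine gene Retn fell by 0.82 (SE 0.16, edgeR adjusted p = 0.0276), and the serine synthesis gene Psat1 fell by 0.54 (SE 0.11, edgeR adjusted p = 0.0299). Lep, which encodes leptin, had 197 ± 75.9 CPM in Fabp4-Ebf2 and 393 ± 135 CPM in wild type and did not pass (edgeR adjusted p = 0.154). The authors' edgeR FDR for Lep was 0.00180. Of 25 pan-adipocyte genes 1 rose, the transcription factor gene Cebpb (log2 fold change 0.83, edgeR adjusted p = 0.0338), and 0 fell. Adjusted over the list alone, 3 rose (Cebpb, Retsat and Aqp7) and 1 fell (Cfd). Cfd had 6864 ± 1847 CPM in Fabp4-Ebf2 and 14009 ± 1342 CPM in wild type, without overlap. It lay just outside the all-gene threshold (edgeR adjusted p = 0.0516), and the authors' edgeR FDR for it was 1.24e-06. Adipoq (log2 fold change -0.41, SE 0.18), Fabp4 (-0.18, SE 0.23) and Pparg (0.29, SE 0.19) did not pass the test. Of 21 genes of lipogenesis and triglyceride synthesis 1 fell, the acyltransferase gene Agpat9 (log2 fold change -0.71, edgeR adjusted p = 0.0408), and 0 rose, whereas adjusted over the list alone 1 rose (Acly) and 1 fell (Agpat9). Of 13 genes described as beige-selective 1 fell, Ear2 (log2 fold change -1.22, edgeR adjusted p = 0.0188), and 0 rose, also when adjusted over the list alone. The beige markers Tmem26, Tnfrsf9 and Tbx1 had log2 fold changes of -0.27, -0.15 and -0.24, none past the test.

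By camera the white-selective list was lower (adjusted p = 5.43e-05, and adjusted p = 0.305 with an estimated correlation) and the lipogenesis list higher (adjusted p = 0.00916, and adjusted p = 0.549 with an estimated correlation). The pan-adipocyte (adjusted p = 0.695) and beige-selective (adjusted p = 0.242) lists did not pass, nor did they with an estimated correlation (adjusted p = 0.888 and 0.343). The mean of the white-selective list was 6.45 ± 0.33 log2 CPM in Fabp4-Ebf2 and 6.92 ± 0.23 log2 CPM in wild type, without overlap, and the difference went from -0.47 to -0.31 without Fabp4-Ebf2 replicate 2. The lipogenesis means overlapped (exact permutation p = 0.171), and without wild type replicate 2 their difference went from 0.49 to 0.29 and the list lost its call (limma's camera, adjusted p = 0.203). Skeletal muscle markers (median log2 fold change -1.99) and extracellular matrix genes (-0.40) were also lower in the same libraries. Only Slc7a10 passed without each single library in turn among these 6 genes. Only 1 member of the white-selective list, instead of 3, passed without wild type replicate 3 or 4 or Fabp4-Ebf2 replicate 1, 3 or 4. The edgeR adjusted p reached 0.0898 for Retn, 0.0929 for Psat1 and 0.108 for Cebpb without wild type replicate 4, 0.112 for Agpat9 without Fabp4-Ebf2 replicate 3, and 0.0570 for Ear2 without wild type replicate 3. Other omissions that ended a call were wild type replicate 3 and Fabp4-Ebf2 replicate 1 for all 5, wild type replicate 4 for Ear2 and Agpat9, Fabp4-Ebf2 replicate 3 for all but Ear2, Fabp4-Ebf2 replicate 4 for Retn, Psat1 and Agpat9, and wild type replicate 1 for Psat1, Agpat9 and Cebpb.

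Interferon-stimulated genes, which cells switch on in antiviral defence, were higher in Fabp4-Ebf2. Of 19 tested members 8 rose, 0 fell and 11 did not pass, and 16 rose when adjusted over the list alone. Ifi44 rose 3.53-fold from 14.2 ± 2.73 to 50.2 ± 15.3 CPM (edgeR adjusted p = 0.00805). The transcription factor gene Irf7 rose 3.70-fold to 520 ± 184 CPM (edgeR adjusted p = 0.0175), Rsad2 rose 5.75-fold to 138 ± 82.7 CPM and Bst2 rose 2.40-fold to 279 ± 67.2 CPM (edgeR adjusted p = 0.0218 each). The list mean was 6.86 ± 0.51 log2 CPM against 5.70 ± 0.35 log2 CPM in wild type, without overlap (exact permutation p = 0.0286), and Fabp4-Ebf2 replicate 2 was the lowest of its group. The list passed camera (adjusted p = 2.26e-13), with adjusted p = 0.239 with an estimated correlation. The skeletal muscle list, at 2.34 ± 0.99 log2 CPM in the same libraries, was lower. Without wild type replicate 3, wild type replicate 4 or Fabp4-Ebf2 replicate 1, 1 member rose each time, with 2 without wild type replicate 1 or Fabp4-Ebf2 replicate 3, 3 without Fabp4-Ebf2 replicate 4 and 13 without Fabp4-Ebf2 replicate 2. Of the genes named here, only Ifi44 passed under each of these omissions, and Irf7 failed without wild type replicate 3 or 4 or Fabp4-Ebf2 replicate 1 (edgeR adjusted p = 0.0526 to 0.0664). Rsad2 and Bst2 failed without those or wild type replicate 1 or Fabp4-Ebf2 replicate 3, and Bst2 also without Fabp4-Ebf2 replicate 4, at edgeR adjusted p of up to 0.0725 and 0.0779.

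Among the markers of other cell types in the depot, those of skeletal muscle had the largest median change. All 20 tested muscle markers had lower means in Fabp4-Ebf2, with a median log2 fold change of -1.99, and 1 fell past the all-gene threshold, the calcium-binding protein gene Casq1 (log2 fold change -2.24, SE 0.51, edgeR adjusted p = 0.0474). Adjusted over the list alone, 16 fell. The fast muscle myosin gene Myh4 had 178 ± 122 CPM in wild type and 38.4 ± 48.3 CPM in Fabp4-Ebf2, neither it nor Acta1 passing on its own. Acta1 was highest in wild type replicate 1 (207 CPM) and, among Fabp4-Ebf2 libraries, in replicate 2 (56.6 CPM). Camera placed the muscle list lower (adjusted p = 4.47e-11, and adjusted p = 0.239 with an estimated correlation). Without Fabp4-Ebf2 replicate 2, 14 muscle markers fell, and 0 fell without any other single library. Casq1 had a log2 fold change of -1.61 without wild type replicate 1. It failed the test without any library except Fabp4-Ebf2 replicate 2, at edgeR adjusted p of 0.0627 to 0.143.

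Lymphocyte (21 tested, median log2 fold change -0.30), endothelial (16, -0.20), erythrocyte (5, -0.64), extracellular matrix (25, -0.40), cell cycle (20, -0.25) and epidermal (4, -0.62) lists were lower by limma's camera, at adjusted p = 2.47e-04, 0.00282, 0.00191, 2.22e-05, 2.56e-04 and 0.0469. With an estimated correlation each lost the call, at adjusted p = 0.460, 0.343, 0.343, 0.343, 0.458 and 0.239 with an estimated correlation. The difference in list means went from -0.26 to -0.10 log2 CPM for lymphocyte and from -0.23 to -0.11 for cell cycle genes without wild type replicate 2, and from -0.40 to -0.20 for extracellular matrix without wild type replicate 1. It went from -0.17 to -0.11 for endothelial genes without wild type replicate 4 and from -0.62 to -0.41 for erythrocyte genes without Fabp4-Ebf2 replicate 1. The epidermal list lost its camera call without wild type replicate 1 or 2 or Fabp4-Ebf2 replicate 1 or 4 (limma's camera, adjusted p = 0.0945, 0.106, 0.0538 and 0.0854). Among their members, the elastin gene Eln fell by 0.65 on the log2 scale (SE 0.11, edgeR adjusted p = 0.0170) and the epidermal gene Sbsn fell by 0.51 (SE 0.10, edgeR adjusted p = 0.0275), and 0 others passed. Adjusted over the list alone, 3 extracellular matrix genes (Eln, Loxl1 and Lox), 4 haemoglobin genes and 1 epidermal gene (Sbsn) fell, with 0 in the other 3 lists. The haemoglobin genes form pairs with identical counts, Hba-a1 with Hba-a2 and Hbb-b1 with Hbb-b2, so that they stand for fewer measurements. Macrophage (18 tested, median log2 fold change -0.00), immediate early and stress (17, 0.14), mammary and simple epithelial (5, 0.23) and creatine and calcium cycling genes (7, 0.00) had 0 members past the test, and their lists did not pass limma's camera (adjusted p = 0.690, 0.368, 0.822 and 0.690). Adjusted over the list alone, Trp63 of the mammary list and Slc6a8 and Ckmt2 of the creatine list fell, with 0 in the others. Median and direction differed for the mammary list, whose camera direction was down, and the creatine list, whose mean log2 fold change was -0.28. In the sympathetic and Schwann cell list 1 of 12 rose, S100b (log2 fold change 2.49, SE 0.56, edgeR adjusted p = 0.0464), while the median was -0.30. In the mesenchymal progenitor and mural list 1 of 17 rose, Dlk1 (1.19, SE 0.25, edgeR adjusted p = 0.0362), with a median of -0.26, and both counts were the same adjusted over the list alone. Neither list passed limma's camera (adjusted p = 0.262 and 0.242), but the Schwann cell list was lower without wild type replicate 2 or Fabp4-Ebf2 replicate 4 (adjusted p = 0.0490 and 0.0370). The immediate early list was higher by limma's camera without wild type replicate 2 or Fabp4-Ebf2 replicate 3 (adjusted p = 0.0230 and 0.0261). S100b lost its call without any library except Fabp4-Ebf2 replicate 2, Dlk1 without any except that and wild type replicate 4, Sbsn without wild type replicate 3 or 4 or Fabp4-Ebf2 replicate 1, 3 or 4, and Eln without wild type replicate 4 or Fabp4-Ebf2 replicate 1 or 4, at edgeR adjusted p of up to 0.125, 0.107, 0.0838 and 0.0623. The log2 fold change of S100b was 1.69 without Fabp4-Ebf2 replicate 3, the library with the most S100b of its group (68.7 CPM).

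**Figure D3:**
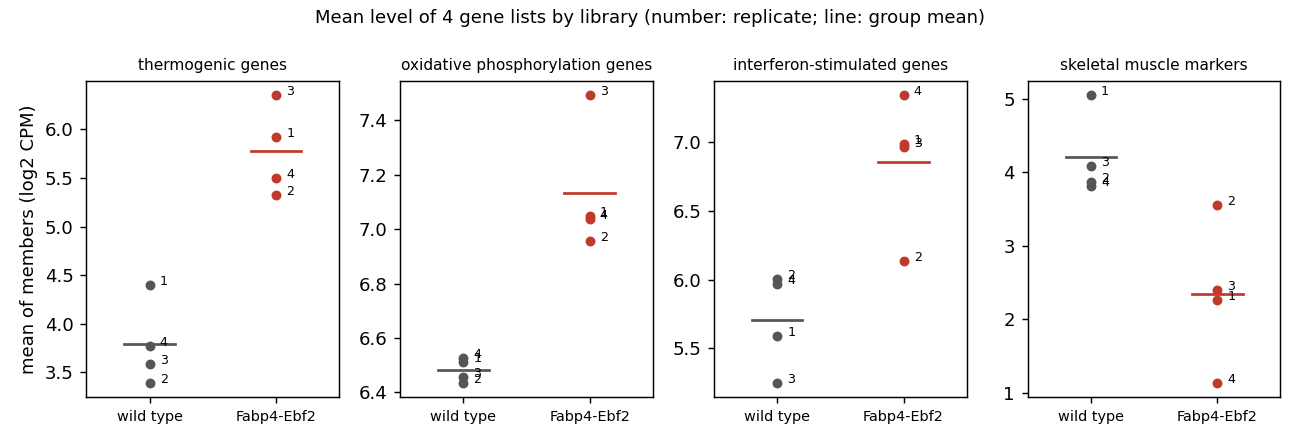
Mean level of the members of 4 gene lists, in log2 CPM, for each library (points numbered by replicate), with lines at the group means. The thermogenic, oxidative phosphorylation and interferon-stimulated lists were higher in all 4 Fabp4-Ebf2 libraries and the skeletal muscle list was lower, with Fabp4-Ebf2 replicate 2 nearest to wild type in each.

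Across the 15002 genes tested, 420 were higher and 93 lower in Fabp4-Ebf2, of which 189 and 35 changed at least 2-fold. The groups did not overlap for 506 of these 513 genes, and for 11.4% of all tested genes, against 2.86% by chance. Beyond Ucp1 and the thermogenic genes Fabp3 (log2 fold change 5.58, SE 0.60), Cpn2 (4.84, SE 0.49) and Slc27a2, the largest rises were in Lgr6, a receptor of the R-spondin family, and A530050N04Rik, a long non-coding RNA also named Lncbate10. These last genes had 548 and 311 reads over the Fabp4-Ebf2 libraries and 6 and 4 over the wild-type libraries, so their folds are imprecise (log2 fold changes 6.52, SE 1.05, and 6.20, SE 1.02). The kininogen gene Kng2 (4.67, SE 0.69) and the ion channel gene Cngb3 (4.59, SE 0.76) completed the 8 largest rises. Among the 8 largest falls were the muscle genes Trdn (-2.59, SE 0.55), Casq1 and Tcap (-2.15, SE 0.47), the potassium channel subunit gene Kcne1l (-1.99, SE 0.27), the cadherin gene Celsr2 (-1.96, SE 0.27) and 1100001G20Rik (-1.88, SE 0.13). The last, also named Wfdc21 or Wdnm1-like, went from 48.8 ± 6.56 to 13.3 ± 1.45 CPM (edgeR adjusted p = 3.35e-04). It was listed as white-selective under its other names and so was not counted with that list. The hair follicle gene Tchh (-1.87, SE 0.32) and the pantetheinase gene Vnn1 (-1.83, SE 0.25) were the others.

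The counts depended on single libraries. There were 248 higher and 54 lower genes without wild type replicate 1, 338 and 181 without replicate 2, 88 and 28 without replicate 3, and 98 and 22 without replicate 4. There were 140 and 25 without Fabp4-Ebf2 replicate 1, 662 and 256 without replicate 2, 251 and 40 without replicate 3, and 220 and 37 without replicate 4. Without either wild type replicate 1, which had the most muscle transcript, or Fabp4-Ebf2 replicate 2, which had the least Ebf2, 513 genes were higher and 164 lower. That fit kept wild type replicate 2, which lay apart from the other wild-type libraries in a principal component analysis of log2 CPM. Its first component was -41.2 against -24.9 to -14.8 in those, and its second was -29.8 against 12.5 to 26.8. Fabp4-Ebf2 replicate 2 was at -23.2 on the second component. With the muscle list as a covariate, 1 gene passed (Impdh1, higher). The mean of that list was 3.81 to 5.04 log2 CPM in wild type and 1.14 to 3.56 in Fabp4-Ebf2, without overlap. The covariate therefore cannot be cleanly separated from genotype. All 513 genes kept their sign in that fit, and the median log2 fold change of the risen genes was 0.87 against 0.92, while their median SE was 0.29 against 0.17. Of the largest changes, Lgr6, A530050N04Rik and Cngb3 did not pass without wild type replicate 3 or 4, and Tchh without these or Fabp4-Ebf2 replicate 1 or 4 (edgeR adjusted p of 0.0533 to 0.0632 for these 4 genes). Trdn failed without any library but Fabp4-Ebf2 replicate 2, and Tcap without any but that and wild type replicate 2, at edgeR adjusted p of up to 0.106 and 0.124. Without Fabp4-Ebf2 replicate 3 the log2 fold changes of Lgr6, A530050N04Rik and Kng2 were 5.34, 5.47 and 3.99, without wild type replicate 1 that of A530050N04Rik was 7.54, and without Fabp4-Ebf2 replicate 2 those of Trdn and Tcap were -3.30 and -2.77.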

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

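The tests of muscle carry-over, muscle read share, immune cell content, a shared batch and the comparison with other omitted Fabp4-Ebf2 libraries were chosen only after the result was seen, and the remaining tests in this part before. Within each group of 4 libraries, the gap between the most extreme library and its nearest neighbour was divided by the group's range, for named genes and lists. Of 242 groups, 19 exceeded the 95% critical value, where chance flags about 1 in 20, or 12.1 groups. They included 5 with wild type replicate 1 as the extreme library and 6 with wild type replicate 2.

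In wild type replicate 1, levels stood above the other wild-type libraries for Trdn (gap over range 0.859), Tnni2 (0.857), Cpt1b (0.886), Acaa2 (0.843) and the creatine and calcium cycling list (0.913). Cpt1b was at 5.44 log2 CPM there, against 3.98 to 4.15 in the other wild-type libraries. In wild type replicate 2, Prdm16 (0.921), Celsr2 (0.870) and Uty (0.909) were low, and Mcm6 (0.889), Bst2 (0.868) and the lymphocyte and lymph node list (0.836) were high. Prdm16 was at 3.41 log2 CPM there against 4.57 to 4.67. In wild type replicate 3, Krtdap was low (0.837) and Hspb1 high (0.857).

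Among Fabp4-Ebf2 libraries, replicate 1 was low for Hoxa9 (0.911) and high for Cdh1 (0.892). Replicate 2 was high for the muscle gene Casq1 (0.845) and low for the white-selective list (0.947), at 5.96 log2 CPM against 6.60 to 6.63. Replicate 3 was high for the oxidative phosphorylation list (0.830), and replicate 4 was low for the endothelial list (0.830).

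The 8 libraries can be split 4 against 4 in 35 ways. For the 420 higher genes only 1 split, the real one, gave as many, and the highest other gave 5. The 93 lower genes likewise had 1 split, with 5 in the highest other. This argues against chance, but 1 of 35 is the smallest share the test can give, so chance is not excluded. Every other split mixes the genotypes, which raises the spread within its groups. The test cannot tell genotype from another difference between the same libraries. Chance also cannot be excluded for the number of gene lists past camera, since 3 splits gave at least the real 14 and the highest other gave 14.

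Skeletal muscle transcripts were lower in Fabp4-Ebf2. A lift of all other genes through the loss of muscle reads was excluded, since the muscle list took at most 0.144% of the reads of any wild-type library. Differing amounts of muscle carried over at dissection may be the cause, since the markers varied together between libraries of 1 group, with a median pairwise correlation of 0.744. Lower muscle gene expression as a result of genotype was not tested and stays open. The adjustment for this list left 1 of 513 calls, with the median log2 fold change of risen genes at 0.87 against 0.92 and their median SE at 0.29 against 0.17, while Ucp1 moved from 5.03 to 7.14 (SE 1.76). That adjustment cannot cleanly separate muscle from genotype, since the list means of the genotypes did not overlap.

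Interferon-stimulated genes were higher in Fabp4-Ebf2. More lymphocytes or macrophages were argued against as the whole explanation. The higher upper quartile of the lymphocyte and macrophage lists was a log2 fold change of 0.09 (0.0913), against a median of 1.21 for the interferon list. Other immune cells were not tested and stay open. Strain variants acting on neighbouring interferon genes were argued against by the 8 called members lying on 7 chromosomes. All 4 Fabp4-Ebf2 libraries lay above every wild-type library, so an effect of genotype and an unlabelled batch, litter or infection shared by the transgenic animals cannot be told apart, because no label separates them.

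Fabp4-Ebf2 replicate 2 lay nearer to wild type: among 662 genes that rose in the other 3 libraries, it reached a median fraction of 0.445 of their rise, with quartiles of 0.230 and 0.590. It reached the mean of the other 3 in 3.17% of these genes and was the lowest of its group in 81.0%, whereas the same measures for each other Fabp4-Ebf2 library left out were 17.3 to 95.2% and 2.79 to 25.5%. Wild-type RNA mixed into this library and a lower transgene level with smaller rises may each be the cause, since both predict these values, and both stay open. Wild type replicate 2 and Fabp4-Ebf2 replicate 2 also shared a low pan-adipocyte mean, 9.59 log2 CPM each against 9.96 to 10.1 in the other libraries. Their macrophage means, 6.95 and 6.88 log2 CPM, were the highest of each group. Such a shared difference, whose source was not tested, stays open as well. Mixing alone would not give the white-selective list of Fabp4-Ebf2 replicate 2, at 5.96 log2 CPM. That value lay below both the other Fabp4-Ebf2 libraries (6.60 to 6.63) and wild type (lowest 6.67, in wild type replicate 2). Nor would mixing give Itih4, chosen after its values were seen, at 7.37 times the rise of the other 3, though a single gene excludes nothing.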

How the results depend on the processing

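Tests chosen only after the data were seen were edgeR's exact test, robust dispersion, other transcript choices, leaving out both doubted libraries, and exact permutation of list means. Ebf2 was higher under all alternatives, with log2 fold changes of 3.47 to 4.35 and of 3.76 to 4.18 over single-library omissions. Its call was lost only with the muscle list as a covariate (3.78, edgeR adjusted p = 0.134), where the SE rose to 0.60 from 0.35. Ucp1 had log2 fold changes of 7.14 (SE 1.76, edgeR adjusted p = 0.381) with the muscle and 4.21 with the lymphocyte covariate, against 5.03 without.

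Against 420 higher and 93 lower genes, DESeq2 called 848 and 385 and edgeR's exact test 727 and 277, each including all 420 and 93. The muscle covariate left 1 and 0, the lymphocyte covariate 168 higher and 131 lower genes, of which 160 and 58 were shared, and a 1.5-fold threshold 53 and 7. With the lymphocyte covariate the median log2 fold change of the risen genes was 0.77 against 0.92, and their median SE was 0.160 against 0.171. The means of that list overlapped between the genotypes, at 6.30 to 6.68 log2 CPM in Fabp4-Ebf2 and 6.52 to 7.21 in wild type. Leaving out both doubted libraries gave 164 lower genes, of which 59 were shared. Single-library omissions gave 88 to 662 higher and 22 to 256 lower genes. Fewer samples lower power, but omitting Fabp4-Ebf2 replicate 2 raised the counts. That library lay nearer to wild type, at a median fraction of 0.445 of the rise of the other Fabp4-Ebf2 libraries, which goes with the higher counts. Why it lay there was not settled. Other normalisations, filters and limma-voom stayed within 1.5 times these counts.

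With replicate number as a block, 475 genes were higher, and 348 of the higher and 69 of the lower genes were shared. Libraries of the same number had correlations of -0.13, 0.33, 0.14 and 0.06 across genes after removal of group means, so the numbers do not pair the libraries throughout. Replicate 2, at 0.33, was the exception, its libraries being each other's best match.

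Of 14 lists past camera, 0 passed with an estimated correlation, 7 with fry and 0 in the exact permutation test. In that test 8 of all 22 lists, among them the creatine and calcium cycling list that did not pass camera, had the smallest possible p of 0.0286 and an adjusted p of 0.0786. Single-library omissions gave 13 to 15 lists, not always the same. Without wild type replicate 2, 12 of 14 were shared, the lipogenesis and epidermal lists being lost and the Schwann cell and immediate early lists gained.

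Of 47 named genes called, 21 lost the call without at least 1 library, all 47 lost it with the muscle covariate, and 0 changed direction under any alternative. The muscle list means of the genotypes did not overlap, so this covariate cannot be cleanly separated from genotype. Calls lost with it do not show that muscle accounts for the changes. By limma-voom Casq1, Cngb3 and S100b lost the call (adjusted p = 0.0630, 0.0675 and 0.109), and without both doubted libraries Psat1, Agpat9 and Dlk1 did (edgeR adjusted p = 0.0819, 0.0698 and 0.0856). With the replicate block Cox8b, Trdn, Tcap, Retn, S100b and Sbsn did (edgeR adjusted p = 0.0505 to 0.0686). The 1.5-fold threshold ended 24 of these calls, Ucp1 among them, the lymphocyte covariate 14, and the mammary covariate 4 (Casq1, Tcap, Agpat9 and S100b). Direction turned only for results that did not pass. Prdm16 had log2 fold changes of 0.10 (0.0994) without both doubted libraries and -0.34 (-0.339) to 0.03 (0.0258) over single omissions. Calml3 reached 0.55 with the muscle covariate, and Ebf1 -0.12 with the lymphocyte covariate and -0.02 (-0.0160) to 0.32 over single omissions. The camera direction turned for 4 lists in some omissions. Their adjusted p over single omissions was 0.159 to 0.982 for pan-adipocyte genes, 0.163 to 0.976 for macrophage markers, 0.171 to 0.944 for mammary markers and 0.0230 to 0.852 for immediate early genes (0.295 without both doubted libraries). The cause was not tested.

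Alternatives for normalised values were not run because the table held counts, nor was sex as a covariate because all libraries expressed Y-linked genes. In simulated data, 40.3% of genes changed 1.5-fold were recovered, so many changes of that size are expected to be missed.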

Other observations

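The families and the neighbour test were chosen as tests only after the result was seen. Of 12 gene families taken by symbol, the mitochondrial ribosomal proteins had 10 of 76 genes higher and 0 lower in edgeR's test, with a median log2 fold change of 0.25 and 71 members with a positive value. Among mitochondrial carriers 4 of 39 rose, including Slc25a34 (log2 fold change 4.17), Slc25a42 (2.05) and Slc25a20 (1.47). Coenzyme Q synthesis genes had 4 of 9 higher (median 0.54) and guanylate-binding proteins, which interferon induces, 5 of 11 (median 0.69). Mitochondrial import genes had 3 of 20 higher and acyl-CoA thioesterases 2 of 9. Positive values also prevailed for proteasome (32 of 38), peroxin (16 of 16) and major histocompatibility class I genes (19 of 22), with medians of 0.14, 0.17 and 0.33. Of these only 1 class I gene, H2-Q10, passed. Class II genes had 0 of 9 positive (median -0.33) and clock genes 6 of 15. Cytosolic ribosomal proteins had 0 past the threshold and a median of -0.26. No scaling alternative took the median of all genes below -0.06. With an estimated correlation, 0 of these families passed limma's camera, with the smallest adjusted p at 0.282.

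Genes past the threshold in the same direction were next to each other more often than chance gave. There were 37 adjacent pairs against a mean of 12.2 and a highest of 25 in 10000 shuffles (permutation p = 1e-04, the smallest they can give). The pairs included Hadha with Hadhb and the run of Adm (log2 fold change 2.45), Ampd3 (1.54), Rnf141 (2.04) and Lyve1 (2.07). Some pairs are copies or overlapping transcripts, such as Oas1h with Oas1g and BC090627 with Cpt1b, so shared reads may account for part of the 37 pairs, and the share was not tested. What links the other pairs, the run from Adm to Lyve1 among them, was not tested either. The rise of such neighbours therefore cannot be assigned to raised Ebf2.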
